A study of Mus musculus with 3 samples.

How the data were processed

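Whole kidneys of male db/m mice on a control diet, db/db mice on a control diet and db/db mice on a 60% fructose diet were profiled by droplet single-cell RNA sequencing, with 1 library per group. Per the labels' protocols, kidneys were perfused, minced and digested with collagenase and pronase, and red cells were lysed and debris and dead cells removed. The deposited values are counts of UMIs per gene and barcode, made by the authors with Cell Ranger 6.0.0 against mm10, per the submitters' processing notes. The files were read as deposited: 32285 genes per library with the same order of genes, 40 symbols shared by more than one gene identifier, and whole numbers throughout. Gene positions were taken by gene identifier from the GENCODE M21 annotation of mm10.

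The deposited barcodes numbered 13524 (db/m), 26513 (db/db control) and 20383 (db/db fructose), with median depths of 1839, 1676 and 1610 UMIs and 706, 643 and 811 genes. Cells were kept with at least 200 genes and at most 50% mitochondrial UMIs. Of the barcodes, 2267, 5292 and 1057 failed the second condition and 18, 58 and 13 the first, with some failing both, leaving 11256, 21218 and 19321 cells. Doublets were scored with Scrublet in scanpy. The automatic Scrublet thresholds called 0%, 10.7% and 25.0% of barcodes, a spread too wide to use, so the highest-scoring barcodes were removed at the expected rate of 0.8% per 1000 barcodes, 10.8%, 21.2% and 16.3% of barcodes. The score separated doublets only weakly, so some doublets remain and some single cells were lost. This left 9946, 16251 and 16046 cells with 22790955, 32371995 and 31957347 UMIs and medians of 766, 711 and 815 genes.

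Counts of the 3 libraries were scaled to 10000 UMIs per cell, log-transformed and clustered together without batch integration: 2000 variable genes, 30 principal components, 15 nearest neighbours and Leiden resolution 1, which gave 32 clusters. Clusters were named from fixed marker lists of 20 classes. A name needed at least 3 markers detected in at least 10% of the cluster's cells and at 2-fold over the other clusters, a mean log2 fold of at least 1.2 over its 10 best markers with 50 CPM added, and a margin of 0.5 over the next class, and none of the other rules on leading genes broken. A first form of this rule was revised after the clusters had been seen, and clusters that fell short stayed unnamed. Macrophage, monocyte and dendritic-like clusters were pooled as mononuclear phagocyte-like, and T, B, natural killer and plasma-like clusters as lymphocyte-like. Differences between any other naming and this one can come from these rebuilt names.

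For each class and library the counts of all cells were summed and expressed as CPM (counts per 1000000 UMIs of that class and library). Cells are not replicates, and with 1 library per group no test was run, no p-value is given and changed genes are not counted over the genome. Each CPM value has an exact Poisson 95% interval, each ratio of 2 sums an exact conditional binomial 95% interval, and each share of cells an exact Clopper-Pearson 95% interval, all for counting error only. A sum of 0 was set to a floor of 3 counts, and the ratio is then a bound. Classes were compared between libraries with at least 100 cells in each. Erythroid-like cells also had that number but are left out, a choice made after they were seen, because they are mainly haemoglobin-filled blood cells.

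The gene lists, 29 in number, were fixed beforehand: fructose uptake and breakdown, gluconeogenesis, glycolysis, glucose and sodium transport, lipid synthesis, cholesterol synthesis and uptake, fatty acid oxidation and PPAR targets, purine and urate handling, nuclear oxidative phosphorylation, the mitochondrial genome, tubular injury, the unfolded protein response, oxidative stress, dissociation and immediate-early genes, inflammatory mediators, interferon response, MHC class II and class I, matrix and fibrosis, endothelial activation, the renin-angiotensin system, distal sodium transport and aldosterone response, male-biased and female-biased proximal tubule genes, early and late proximal segments, ribosomal proteins, cell cycle and leptin signalling. A member was measured at 10 CPM or more in either library and counted as higher or lower at a ratio of 1.5-fold or more. The median log2 ratio of a list was placed among 10000 random lists of the same size matched on mean expression.

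Genes were named by a rule fixed beforehand. In proximal tubule-like cells it took the 8 highest and 8 lowest ratios among genes with at least 50 CPM in the higher library and up to 3 members of each of 8 main lists, and in the other classes the 3 highest and 3 lowest with at least 20 counts. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and unnamed gene models were left out, as were genes under 25% of their highest class in both libraries. The highest class was sought only among named classes with at least 50 cells in every library. Members of the fixed lists were added as examples in order of absolute ratio, as were Slc2a5, Khk, Slc5a2, Havcr1, Lcn2 and Vcam1 and the label-check genes. Some genes that these rules take are not reported here, so the order of examples holds for the genes named. For classes other than the proximal tubule, 4 of the 29 lists are described, chosen after their values were seen.

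Each count was recomputed under 15 other settings, 7 of which apply to shares. The 13 planned settings were at most 30% mitochondrial UMIs, at least 500 genes, doublets kept, Leiden resolutions 0.5 and 2, each library clustered on its own, the mean over cells, median-of-ratios size factors, mitochondrial genes left out of the total, cells thinned to 1000 UMIs, minimums of 1 and 50 CPM, and a free-RNA profile subtracted. The automatic Scrublet thresholds and the restriction to cells with 10 to 20% mitochondrial UMIs were added after seeing the data. Thinning left out 1087, 289 and 1239 of the proximal tubule-like cells. Free RNA was estimated from proximal tubule markers in 96, 82 and 101 lymphocyte-like cells, where their share of UMIs was 50.4%, 53.7% and 63.3% of that in the whole library. Doublets left among these cells can raise the estimate. The profile subtracted from a class also includes that class's own UMIs, so the subtraction can remove too much, above all in proximal tubule-like cells.

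The ratios, intervals and list measures were tested on simulated Poisson counts with the real means and totals and 200 genes changed by known folds. The simulation held counting error only, so coverage near 95% was built in. It had no variation between mice or libraries, no mitochondrial shift and no free RNA, and its rates are not error rates of the real comparisons. For proximal tubule-like cells, db/db control against db/m, 8295 genes were simulated: the interval held the true ratio for 95.4% of unchanged genes, 0.0371% of unchanged genes were called 1.5-fold, and 46.3% of 1.5-fold, 100% of 2-fold and 100% of 4-fold changes were called. For fructose against control in db/db, with 8602 genes, these values were 95.6%, 0.0714%, 49.3%, 100% and 100%. For intercalated-like cells, the smallest of the 6 classes compared in the report, 13.8% of unchanged genes were called 1.5-fold for db/db control against db/m (8729 genes) and 11.7% for fructose against control (8960 genes), so single 1.5-fold differences there lie within counting error. These rates were not measured for the smaller mononuclear phagocyte-like and thin limb-like classes. A simulated list of 15 changed genes had 15 members higher at percentile 100 in each of these 4 comparisons, and an unchanged list had 0.

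The computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.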

Results

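Kidneys of male mice were profiled by droplet single-cell RNA sequencing at 28 weeks of age, in 3 groups. The db/db mouse lacks a working long form of the leptin receptor and becomes obese and diabetic, whereas db/m mice carry a normal copy of the gene beside the mutant one and stay lean. The db/m group and 1 db/db group had a fructose-free control diet, and the other db/db group had a diet with 60% fructose, in each case from 8 weeks of age for 20 weeks. Each group gave 1 library, and the number of mice behind a library is not known here. The db/m library held 13524 barcodes with 31660184 UMIs, the db/db control library 26513 barcodes with 52704335 UMIs, and the db/db fructose library 20383 barcodes with 42028885 UMIs. With 1 library per group no difference has a replicate check and nothing was tested, and every 95% interval below covers counting error only.

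After filtering, 9946, 16251 and 16046 cells remained in the db/m, db/db control and db/db fructose libraries, with medians of 1682, 1629 and 1532 UMIs per cell. Clusters were named by fixed marker lists, so each name means cells like that type. The median share of mitochondrial UMIs was 15.1%, 24.7% and 10.6% in the kept cells, and this share moved with the groups in every class compared here.

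Proximal tubule-like cells, the segment that reclaims glucose, amino acids and most of the filtered sodium, made up 59.0% of db/m cells (95% interval 58.0 to 60.0), 40.2% of db/db control cells (39.5 to 41.0) and 53.7% of db/db fructose cells (52.9 to 54.5). Thick ascending limb-like cells were 12.4%, 12.3% and 14.8%, distal convoluted tubule-like cells 6.998%, 11.2% and 7.39%, and connecting tubule and principal-like cells 7.17%, 5.28% and 5.45%. Endothelium-like cells were 4.67%, 5.98% and 5.83%, intercalated-like cells 2.08%, 3.37% and 2.58%, and thin limb-like cells 1.62%, 0.443% and 1.12%. Mononuclear phagocyte-like cells made up 0.865% of db/m cells (0.692 to 1.07), 2.16% of db/db control cells (1.94 to 2.40) and 1.92% of db/db fructose cells (1.71 to 2.14). Lymphocyte-like cells were 0.965%, 0.505% and 0.629%. Neutrophil-like cells numbered 4, 23 and 42, erythroid-like cells were 1.33%, 0.677% and 0.654%, and pericyte, mesangial and smooth muscle-like cells numbered 22, 26 and 24. Podocyte-like cells, which form the filtration barrier of the glomerulus, numbered 103 in db/m (1.04%, 0.846 to 1.25), 8 in db/db control (0.0492%, 0.0213 to 0.0970) and 12 in db/db fructose (0.0748%, 0.0386 to 0.131). Clusters that met no naming rule held 1.64%, 17.5% and 5.46% of cells, so each named share in db/db control is set partly by these cells. The threshold for names was set after the clusters had been seen.

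**Figure D1:**
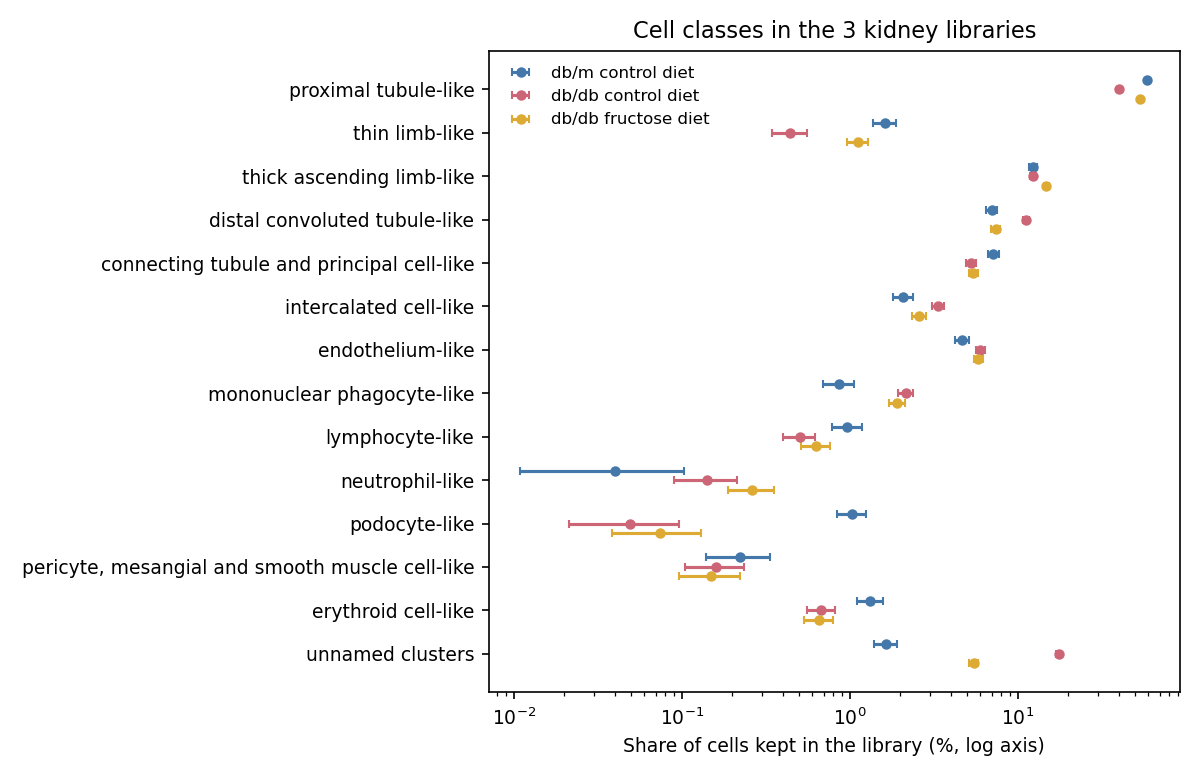
Share of kept cells in each named class and in unnamed clusters, in percent on a log axis, for the db/m control, db/db control and db/db fructose libraries, with exact 95% binomial intervals (counting error only). Proximal tubule-like cells are the largest class in each library, at 59.0%, 40.2% and 53.7%.

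The sex label was met in each library: the Y-linked genes Ddx3y and Eif2s3y gave 1085, 1665 and 1953 counts and 1470, 2025 and 2690 counts, Uty gave 842, 1168 and 1559, Kdm5d gave 726, 1022 and 1218, and Xist gave 6, 8 and 10. Lepr, the leptin receptor gene that carries the db mutation, gave 14, 10 and 15 counts over all kept cells. The 3′ tag of Lepr may lie outside the part that the mutation changes, so these counts check nothing about genotype.

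The comparison of db/db with db/m mice on the control diet addresses how the diabetic genotype differs in each kidney cell class. In proximal tubule-like cells, genes that male mice express more strongly than female mice were lower in db/db: 13 of 14 measured members of the male-biased list were at least 1.5-fold lower and 0 higher, with a median log2 ratio of -2.57. Kap, the kidney androgen-regulated protein gene, stood at 5466 CPM (counts per 1000000 UMIs of the class) in db/m and 102 in db/db. The highest ratio of the genes reported here belonged to Cyp4a14, a gene of fatty acid omega-oxidation that PPAR alpha drives, which stood at 2.59 CPM in db/m and 251 in db/db, 96.9-fold higher. Cholesterol synthesis and uptake was lower for 7 of 13 genes, the unfolded protein response for 9 of 14, and genes of the late proximal segment for 9 of 11, with 0 higher in each of these lists. Over the other settings 2 (minimum of 50 CPM, 4 members measured) to 11 cholesterol genes (at most 30% mitochondrial UMIs, 15 measured) were lower in proximal tubule-like cells. The proximal tubule-like cells came mostly from clusters 7, 9 and 10 in db/m, 0 and 2 in db/db control, and 1 and 3 in db/db fructose, with median mitochondrial shares of 14.5%, 20.9% and 9.25%.

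Log2 ratios are followed by their exact 95% intervals in brackets for the genes that lead each group, and CPM values are in the order db/m, db/db control and db/db fructose. Gene positions are in the mm10 build. Where genes of a class are ordered as a whole, the order holds within set limits: at least 50 CPM in the higher library and at least 25% of the level of their highest class in either library, and outside the proximal tubule at least 20 counts. The highest class was sought only among named classes with at least 50 cells in every library. Neutrophil-like, podocyte-like, and pericyte, mesangial and smooth muscle-like cells and unnamed clusters were not among them, so free RNA from these cells can pass the limits. Members of lists are also given from outside these limits, and their ratios can be more extreme. The median log2 ratio of all measured genes in proximal tubule-like cells lay close to 0 for db/db control over db/m. Scaling by median-of-ratios size factors in place of CPM moved all ratios by -0.03 on the log2 scale, and list counts are given under that scaling wherever they differ. The percentile of a list places its median among 10000 random lists of matched expression, and describes these libraries only.

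Slco1a1, an organic anion transporter gene (ENSMUSG00000041698, chromosome 6, 141907282 to 141946962), had the lowest ratio of genes within the limits (-7.84 [-8.85 to -7.00]), with 228, 0.991 and 10.4 CPM. Kap (ENSMUSG00000032758, chromosome 6, 133849851 to 133853762) followed within the limits at -5.74 [-5.83 to -5.66], and its level in db/db fructose was 329 CPM. The other genes at the low end were Ldc1, a leucine decarboxylase gene (-5.54), Slc7a13, an amino acid transporter of the late segment (-4.57 [-4.86 to -4.29]; 231, 9.73 and 49.4 CPM), Acsm3, a medium-chain acyl-CoA synthetase (-4.12), Cndp2, a cytosolic dipeptidase (-3.46), Cd36, a fatty acid translocase (-3.40), and Acy3, an aminoacylase (-3.02). At the high end stood Cyp4a14, a fatty acid omega-hydroxylase (ENSMUSG00000028715, chromosome 4, 115486200 to 115496142), with 6.60 [6.06 to 7.19]. Cyp24a1, which inactivates vitamin D, was at 60.7, 532 and 432 CPM (3.13 [3.01 to 3.25]). Gprin3 (3.12), Rdh16f2 (2.82), the efflux pump gene Abcc4 (2.38), Wsb1 (2.10) and Svopl (1.99) were also at the high end.

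Fructose uptake and breakdown was split, with 4 of 12 members higher and 3 lower (median 0.06, percentile 75.7). Slc2a5, the fructose transporter GLUT5 (ENSMUSG00000028976, chromosome 4, 150119283 to 150144169), was higher in db/db (1.78 [1.52 to 2.04]; 14.97, 51.4 and 56.7 CPM), as was Slc5a10, a sodium-coupled sugar transporter (1.46 [1.33 to 1.59]; 58.9, 162 and 286 CPM), while Akr1b3, the aldose reductase gene, was lower (-1.36). Khk, which phosphorylates fructose, differed little (-0.06 [-0.13 to 0.01]). Gluconeogenesis had 2 higher and 2 lower of 13 (median 0.09, percentile 85.7), with Ppargc1a at 0.95 and Mpc1 at -0.72. Glycolysis had 4 higher and 1 lower of 15, or 3 and 2 with size factors, led by Pklr (1.51) and Pkm (1.51). Of the glucose and sodium transport genes, 5 were higher and 3 lower of 12 (4 and 3 with size factors; median 0.45), with Slc9a8 at -1.02, Slc5a1 (SGLT1) at 0.99 and Slc5a2 (SGLT2) at 0.45 [0.41 to 0.49].

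Fatty acid oxidation and PPAR targets had 8 members higher and 3 lower of 24 (median 0.30, percentile 99.9), with Cyp4a14 and Cd36 among the most extreme. Lipid synthesis was balanced at 2 higher and 2 lower of 15 (median 0.03), with malic enzyme Me1 at -1.65, Gpam at 0.94 and the lipogenic regulator Srebf1 at -0.84. Cholesterol synthesis and uptake had a median of -0.66 (percentile 0) and 8 of 15 members lower with size factors. Its most extreme members were Cyp51, the lanosterol demethylase (-1.97 [-2.21 to -1.73]; 66.0, 16.9 and 34.6 CPM), Idi1 (-1.66) and Mvd (-1.35). Purine and urate handling had 2 higher and 7 lower of 11 (median -0.64), including the ecto-nucleotidase Nt5e (-1.64) and the urate transporter Slc17a3 (-1.13).

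Of the 22 nuclear genes of oxidative phosphorylation, 2 were lower and 0 higher (median -0.31; Cycs -1.27), and of the 13 genes of the mitochondrial genome 1 was higher (median 0.21; mt-Atp8 0.81). Ribosomal protein genes were lower for 47 of 77, or 56 with size factors (median -0.64; Rps27l -1.11). The unfolded protein response had a median of -0.79, with Manf (-1.20), Sdf2l1 (-1.20) and the chaperone Calr (-1.16) lowest.

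Oxidative stress genes went both ways, 5 higher and 9 lower of 20 (5 and 10 with size factors; median -0.53). Gsta2, a glutathione transferase (ENSMUSG00000057933, chromosome 9, 78331018 to 78355788), was at 1.94, 48.3 and 6.76 CPM (4.64 [4.01 to 5.34]), Hmox1, the haem oxygenase (ENSMUSG00000005413, chromosome 8, 75093621 to 75100589), at 9.79, 32.3 and 5.02 CPM (1.72 [1.40 to 2.05]), and the metallothionein Mt2 at 1.71. Hmox1 stood at 57.1, 184 and 54.6 CPM in mononuclear phagocyte-like cells, so free RNA is not excluded as a source of its ratio here. Dissociation and immediate-early genes had 1 higher and 6 lower of 21 (median -0.09; Hsp90aa1 -1.14).

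Tubular injury genes had 5 higher and 3 lower of 14 (4 and 3 of 16 with size factors; median 0.16). Il34, a macrophage growth factor gene, was lowest (-3.79 [-4.72 to -2.98]), and the complement gene C3 (ENSMUSG00000024164, chromosome 17, 57203970 to 57228136) and the secreted chaperone Clu were highest (2.16 [1.78 to 2.56] and 2.002 [1.82 to 2.19]; 6.28, 28.1 and 69.1 CPM, and 27.3, 109 and 106 CPM). With at most 30% mitochondrial UMIs the C3 ratio was -0.0038. Havcr1, which encodes the injury marker KIM-1, gave 1, 2 and 9 counts, and Lcn2, the lipocalin NGAL (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252), 1, 26 and 71 counts in the 3 libraries (Lcn2 log2 ratio 4.66 [2.06 to 10.02]). Lcn2 reached at most 3.47% of its highest class in these cells, and free RNA is not excluded as the source of its ratio in either comparison. Vcam1, an adhesion molecule of injured tubules, was at 4.90, 3.06 and 8.29 CPM (-0.68 [-1.34 to -0.03]; 0.16 with each library clustered on its own). Thin limb-like cells that took the proximal tubule name at Leiden resolution 2 held 30, 0 and 21 further Havcr1 counts. They also held 162, 31 and 96 Vcam1 counts, so no order of the libraries is drawn for either gene.

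Few immune genes were measured in this class. Inflammatory mediators had 2 of 5 higher (Cxcl10 1.16), interferon response 1 of 4 (2 of 5 with size factors; Irf1 0.65), and MHC class II antigen presentation 0 of 4 (H2-Aa 0.31, a gene at no more than 0.196% of its highest class here), with 0, 0 and 0 lower. MHC class I had 1 lower of 7 (B2m -0.63), matrix and fibrosis 2 lower of 6 (Ccn2 -0.88), and neither had a higher member, but with free RNA subtracted matrix and fibrosis had 3 higher and 1 lower in proximal tubule-like cells, and no MHC class I or class II member was measured any longer. Endothelial activation genes had 3 higher and 1 lower of 4 (Cxcl12 1.08). Cell cycle had 1 lower of 4 (Stmn1 -1.31) and leptin signalling 1 lower of 5 (Socs2 -1.75).

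Among the hormone-related lists, the renin-angiotensin genes had 1 higher and 3 lower of 8 (1 and 4 with size factors), with Ace, the angiotensin-converting enzyme, at -2.70 [-3.11 to -2.31] (36.3, 5.59 and 9.81 CPM). Of the distal sodium transport and aldosterone response genes, 8 were higher and 1 lower of 17 (median 0.54), led by the kinase Sgk1 (1.83 [1.73 to 1.93]; 89.3, 318 and 167 CPM), Klhl3 (1.36) and Stk39 (1.11). This list holds transcripts of distal segments, such as Klhl3, a leading gene of distal convoluted tubule-like cluster 6. That class was 6.998% of db/m and 11.2% of db/db control cells, so free RNA can enter this count. The male-biased list (percentile 0; 14 of 14 lower with size factors) also held Hsd11b1 (-4.97), which regenerates active glucocorticoid. The female-biased list had 2 higher and 1 lower of 4, with Cyp4a14, the prolactin receptor Prlr (4.17) and Tmigd1 (-2.69), and 2 higher and 4 lower at a minimum of 1 CPM.

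Early segment genes (S1 and S2) had 2 higher and 1 lower of 11 (1 and 1 with size factors; Slc2a2 0.72). The late segment (S3) list had a median of -1.94. Slc22a7, an organic anion transporter, was lowest: 19.4 CPM in db/m and 0 counts in db/db, at least 71.8-fold lower against a floor of 3 counts, and Slc7a13 and Acy3 followed. By segment markers, late cells were 68.5% of the db/m and 32.9% of the db/db proximal tubule-like cells that could be placed. The late markers used belong to this same list, so these shares are not an independent count of segments. The counts of injury and immune genes depended on which cells were kept and which took the proximal tubule name. With at most 30% mitochondrial UMIs and cells clustered anew, tubular injury had 3 higher and 12 lower of 21 in proximal tubule-like cells. Interferon response had 1 and 2 of 6, inflammatory mediators 0 and 3 of 7, endothelial activation 1 and 2 of 5, and MHC class II 0 and 5 of 5. Requiring 500 genes per cell or clustering at resolution 2 turned the injury list likewise, to 3 higher and 11 lower of 21 in proximal tubule-like cells, so no direction is drawn for these lists in db/db against db/m.

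**Figure D2:**
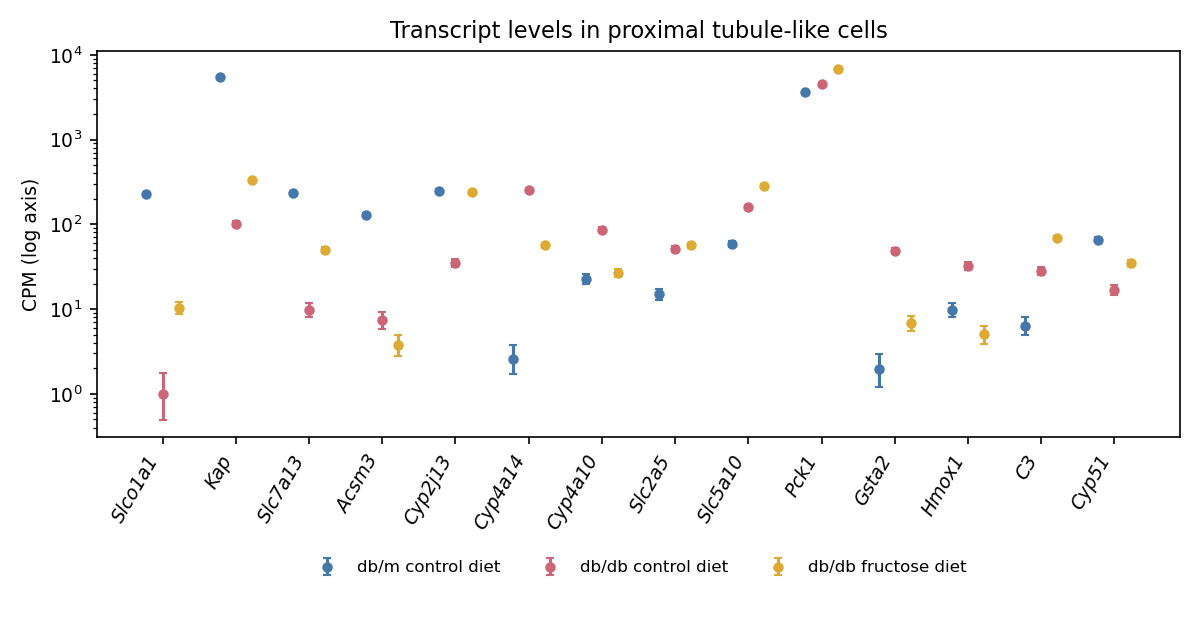
Expression of named genes in proximal tubule-like cells, in CPM on a log axis, for the db/m control, db/db control and db/db fructose libraries, with exact 95% Poisson intervals (counting error only). Kap and Slco1a1 are highest in db/m, while Cyp4a14 is highest in db/db control at 251 CPM.

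In the other classes 4 lists are given, chosen after their values were seen. Kap, Slco1a1 and Slc7a13 were among the lowest genes within the limits in 4 of these 5 classes. They are proximal tubule transcripts, as are Acy3, Cyp2e1, Slc2a2, Slc22a12 and Acsl1, named below in classes where they reached at most 25.5% to 34.5% of their highest class. Proximal tubule markers in lymphocyte-like cells stood at 50.4%, 53.7% and 63.3% of their library-wide level. This estimates the free RNA that such values include, although remaining doublets can raise it. Ratios of these genes outside the proximal tubule are therefore not read as changes of the class named. Thick ascending limb-like cells, which reabsorb salt and dilute the urine, had 7 tubular injury genes higher and 0 lower of 17 (8 of 18 with size factors). C3 gave 1 count in db/m and a log2 ratio of 5.203 [2.66 to 10.53], Lcn2 stood at 3.49, 30.2 and 135 CPM (3.11 [2.19 to 4.21]) and Clu at 69.1, 378 and 1012 CPM (2.45 [2.24 to 2.67]). Nefl, a neurofilament gene, had the highest ratio within the limits (3.02 [2.48 to 3.62]), followed by Clu and Adgrg3 (1.78). The class included cluster 22, with Nos1 and Pappa2 among its leading genes, at 55, 185 and 163 of 1232, 1999 and 2376 cells. Nefl was a leading gene of a Nos1 cluster when db/db control was clustered on its own. Whether the Nefl ratio follows the share of such cells was not tested. Fatty acid oxidation and PPAR targets had 7 higher and 1 lower of 24, cholesterol genes 0 and 3 of 13 (5 of 15 lower with size factors; Mvd -0.99), and interferon response 1 and 0 of 4 (1 and 1 of 5; Bst2 0.90). With free RNA subtracted the cholesterol list turned to 3 higher and 0 lower in the thick ascending limb, with Mvd at 0.00069.

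In distal convoluted tubule-like cells, where the all-gene median was -0.18 and size factors moved ratios by 0.16, the highest ratios within the limits were those of the calcium-binding protein gene S100g (1.76 [1.65 to 1.87]; 574, 1943 and 4420.0 CPM), Pdk4, which restrains glucose oxidation (1.05 [0.85 to 1.26]), and the calbindin gene Calb1 (1.04). The class pooled clusters 6 and 12, with 473 and 223 cells in db/m, 1139 and 680 in db/db control, and 894 and 291 in db/db fructose. S100g was a leading gene of cluster 12 and not of cluster 6, and ratios within each cluster were not examined. S100g and Calb1 are also markers of the connecting tubule, so cells or free RNA of that segment are not excluded as a source. Cholesterol genes were lower for 11 of 14 (9 with size factors) and higher for 0, led by Fdps (-1.93 [-2.52 to -1.36]), Insig1 (-1.58) and Idi1 (-1.57). Fatty acid oxidation had 6 higher and 3 lower of 24 (7 and 1), tubular injury 1 and 2 of 15 (3 and 1), and interferon response 2 and 0 of 5 (3 higher), with size-factor counts in parentheses. C3 gave 0 counts in db/m here, a log2 ratio of at least 2.57 against the floor of 3 counts. The injury list turned to 5 higher and 3 lower with at most 30% mitochondrial UMIs and to 3 higher and 2 lower with free RNA subtracted, and fatty acid oxidation to 1 and 3 at a minimum of 50 CPM.

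Connecting tubule and principal-like cells (all-gene median -0.15) had Ltc4s, the leukotriene C4 synthase (2.36 [1.74 to 3.02]; 9.78, 50.04 and 25.2 CPM), the calcium pump Atp2b4 (2.16) and the sodium-calcium exchanger Slc8a1 (1.81) highest within the limits, and Kap (-4.68), Acy3 (-2.17) and Cyp2e1 (-1.98) lowest. The class pooled clusters 11 and 14, with 398 and 315 cells in db/m, 684 and 174 in db/db control, and 571 and 304 in db/db fructose. Slc8a1 was a leading gene of cluster 11 and not of cluster 14, and ratios within each cluster were not examined. Tubular injury had 4 higher and 2 lower of 16 (5 and 1 of 17 with size factors), with osteopontin, Spp1, at 1.81 [1.70 to 1.91] and Clu at 1.53 [1.41 to 1.66]. Interferon response was lower for 6 of 10 and higher for 0, led by Gbp2 (-2.61 [-4.32 to -1.25]) and Isg15 (-1.40). Fatty acid oxidation had 7 higher and 1 lower of 23 (9 and 1 of 24), and cholesterol genes 0 and 5 of 9 (Idi1 -1.06). Free-RNA subtraction turned fatty acid oxidation to 1 higher and 3 lower and Kap to 3.42 in this class, keeping doublets turned injury to 3 and 4, and among cells with 10 to 20% mitochondrial UMIs Gbp2 was at 0.45.

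Endothelium-like cells had lower interferon response genes in db/db, 8 of 19 and 0 higher. The median mitochondrial share of this class was 9.62% in db/m and 18.0% in db/db control. On fructose, against the same db/db control library, the list did not keep its direction among cells with 10 to 20% mitochondrial UMIs. Its counts for db/db against db/m among such cells are not given here. Ifi27l2a was at 67.7, 11.9 and 89.2 CPM (-2.51 [-3.16 to -1.89]), the ubiquitin-like Isg15 at 117, 42.3 and 94.0 CPM (-1.47 [-1.84 to -1.10]) and the interferon regulator Irf7 at 55.5, 21.8 and 57.5 CPM (-1.35 [-1.89 to -0.82]). The protease inhibitor gene Serpine2 (1.54), the phosphatase Ptprj (1.53) and Gpihbp1, which anchors lipoprotein lipase to capillaries (1.53 [1.33 to 1.73]; 183, 529 and 735 CPM), had the highest ratios within the limits. Fatty acid oxidation had 9 higher and 1 lower of 24 (12 and 1 with size factors), cholesterol 0 and 4 of 13 (3 lower; Cyp51 -1.14), and tubular injury 3 and 4 of 17 (5 and 4; C3 4.199 [1.62 to 9.54], Cp -1.55). Serpine2 was also a leading gene of an unnamed cluster, and its level there was not part of the limits. In endothelium-like cells free-RNA subtraction turned cholesterol to 2 higher and 1 lower, Cyp51 to 0.38 and C3 to -0.70. Among endothelium-like cells with 10 to 20% mitochondrial UMIs cholesterol had 5 higher and 4 lower, and injury turned to more higher than lower members in 6 settings.

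Intercalated-like cells, the acid-base cells of the collecting duct, had 6 injury genes higher and 0 lower of 15 (Clu 1.41 [1.11 to 1.71]), 9 fatty acid oxidation genes higher and 2 lower of 24 (10 higher with size factors), 8 cholesterol genes lower and 0 higher of 13 (6 lower; Idi1 -1.23), and 1 interferon gene higher and 1 lower of 7. Slc2a2 (1.65), Zfp451 (1.46) and Clu had the highest ratios within the limits, and Slc2a2 is a proximal tubule gene that reached at most 26.9% of its highest class here. Median mitochondrial shares in db/m and db/db were 21.2% and 25.6% in thick ascending limb-like, 17.6% and 29.0% in distal convoluted tubule-like, 17.5% and 26.3% in connecting tubule and principal-like, 9.62% and 18.0% in endothelium-like, and 16.2% and 22.7% in intercalated-like cells.

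The comparison of the fructose with the control diet within db/db addresses what a long fructose load adds to the diabetic kidney. In proximal tubule-like cells some PPAR-driven genes were lower on fructose, with Cyp4a14 at 251 and 56.3 CPM and 7 of 24 genes of the fatty acid oxidation list at least 1.5-fold lower against 2 higher (10 and 1 of 24 with size factors). Cholesterol synthesis and uptake was higher for 9 of 14 genes and lower for 0 (5 and 0 of 13 with size factors). Dissociation and immediate-early genes, which also respond to tissue handling, had 11 higher and 0 lower of 19 (8 and 1 of 20). Clock genes also differed between these libraries, and whether these lists follow the clock phase was not tested. Male-biased genes were higher for 10 of 12 (6 higher and 1 lower of 11 with size factors), and the clock genes Nr1d1 and Per3 stood 5.32-fold and 4.62-fold higher. Hmox1 and Gsta2 were lower (-2.69 and -2.84). Hmox1 was also lower in mononuclear phagocyte-like cells, at 184 and 54.6 CPM, and free RNA is not excluded as a source of its ratio. The fructose transporter Slc2a5 was at 51.4 and 56.7 CPM in the control and fructose libraries (0.14 [-0.02 to 0.30]), a difference not detectable at this depth.

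All 13 measured genes of the mitochondrial genome were lower on fructose (median -0.91; mt-Co1 -1.18, mt-Atp8 -1.17), and the median mitochondrial share of proximal tubule-like cells was 20.9% on the control diet and 9.25% on fructose. The median log2 ratio of all measured genes was 0.26. Size factors moved all ratios by -0.27 on the log2 scale, so the counts under size factors, which stand close to counts relative to the median gene, are given beside each list in parentheses after the CPM counts. Both comparisons contain the db/db control library, so opposite signs in them can come from that library alone.

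Cyp2j13, a cytochrome P450 gene (ENSMUSG00000028571, chromosome 4, 96027534 to 96077546), had the highest ratio of genes within the limits (2.78 [2.63 to 2.94]; 248, 34.9 and 240.3 CPM). Nr1d1, the clock repressor REV-ERB alpha (ENSMUSG00000020889, chromosome 11, 98767932 to 98775333), was at 11.3, 19.4 and 103 CPM (2.41 [2.20 to 2.62]), and Per3, a period gene (ENSMUSG00000028957, chromosome 4, 151003652 to 151044665), at 24.6, 19.5 and 89.9 CPM (2.21 [1.997 to 2.42]). Ugt8a (1.93), Nat8f6 (1.79), Slc22a30 (1.78), Gria3 (1.71) and Kap (1.69 [1.60 to 1.78]) completed the 8 highest within the limits. The transcriptional repressor gene Bcl6 was lowest within them (-2.31 [-2.51 to -2.11]; 28.8, 93.2 and 18.8 CPM), followed by Cyp4a14 (-2.16 [-2.27 to -2.04]) and its neighbour Cyp4a10 (-1.71; chromosome 4, 115518264 to 115533649). Lgals4, a galectin (-1.18), Ehhadh, the peroxisomal bifunctional enzyme (-1.04 [-1.22 to -0.87]; 134, 66.4 and 32.2 CPM), Nrg1, a neuregulin (-1.03), and Acsl1, a long-chain acyl-CoA synthetase (-0.98), were also at the low end.

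Fructose uptake and breakdown had 2 higher and 0 lower of 12 (1 and 0), led by Glyctk, a glycerate kinase (0.99), Slc5a10 (0.82 [0.74 to 0.90]) and Fbp1 (0.55). The list had 5 higher with at most 30% mitochondrial UMIs, with at least 500 genes, at Leiden resolution 2 and with each library clustered alone. Its median of 0.25 was at percentile 55.7, with Khk at 0.28 [0.22 to 0.34]. Gluconeogenesis had 3 higher and 0 lower of 13 (0 and 0; percentile 99.4), with Foxo1 (0.77) and the rate-limiting Pck1 (0.61 [0.60 to 0.63]; 3622, 4497 and 6875 CPM). Glycolysis had 0 higher and 1 lower of 15 (0 and 3; Pkm -0.68), and glucose and sodium transport 1 and 0 of 12 (0 and 1; Slc9a8 0.67). Slc5a2 was at 0.42 [0.38 to 0.45].

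Lipid synthesis had 1 higher and 2 lower of 15 (1 and 3), with the desaturase Scd2 at -0.99 [-1.24 to -0.75], Lpin1 at 0.97 [0.85 to 1.09] and Acacb, an acetyl-CoA carboxylase, at -0.77. The fatty acid oxidation list had a median of -0.27 (percentile 0; 1 higher and 10 lower with size factors), with Cyp4a14 and Cyp4a10 lowest. Cholesterol synthesis and uptake (median 0.66; 5 and 0 of 13) included Insig1 (1.23) and the squalene epoxidase Sqle (1.15). Purine and urate handling had 1 higher and 0 lower of 11 (1 and 1; Slc17a3 0.90), but 0 and 1 among proximal tubule-like cells with 10 to 20% mitochondrial UMIs. Lipid synthesis turned to 3 higher and 2 lower at a minimum of 1 CPM and to 1 and 0 at 50 CPM.

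Nuclear oxidative phosphorylation genes had 0 higher and 0 lower of 22 (0 and 0; Ndufs1 0.35), ribosomal protein genes 1 and 0 of 77 (0 and 2; Rpl22l1 0.75), and the unfolded protein response 0 and 0 of 13 (0 and 1; Hspa5 -0.57). Oxidative stress genes had 1 higher and 6 lower of 20 (0 and 8), with Gsta2 (-2.84 [-3.17 to -2.52]), Hmox1 (-2.69 [-3.08 to -2.31]) and the metallothionein Mt1 (-0.92 [-0.99 to -0.84]) lowest. Dissociation and immediate-early genes (median 0.68; 8 and 1 of 20) were led by Egr1 (1.35 [1.26 to 1.45]), Junb (1.22) and Fosb (1.21). With free RNA subtracted ribosomal protein genes had 0 higher and 14 lower in proximal tubule-like cells (Rpl22l1 -3.43).

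Tubular injury genes had 9 higher and 1 lower of 18 (3 and 2 of 17; median 0.57), led by ceruloplasmin, Cp (1.57 [1.12 to 2.04]; 8.59, 4.69 and 13.9 CPM), the fibrinogen gene Fga (1.31) and C3 (1.30 [1.11 to 1.49]). With free RNA subtracted this list had 3 higher and 3 lower in proximal tubule-like cells, with Cp at -0.74. Lcn2 was at 1.14 [0.47 to 1.85] and Vcam1 at 1.44 [0.87 to 2.03]. The Vcam1 ratio leaves out thin limb-like cells that took the proximal tubule name at Leiden resolution 2, with 31 and 96 Vcam1 counts. Inflammatory mediators had 3 higher and 0 lower of 6 (2 and 0), led by the chemokine genes Cxcl16 (1.08) and Cxcl1 (1.04), and interferon response 2 and 0 of 5 (2 and 0), led by Ifi27 (1.23) and Ifitm3 (1.09). The interferon members higher numbered 1 with free RNA subtracted, 5 at Leiden resolution 2 and 6 at a minimum of 1 CPM. MHC class II had 2 higher and 0 lower of 4 (0 and 0; H2-Ab1 0.81, Cd74 0.70), and MHC class I 6 and 0 of 8 (0 and 0; Tap2 0.84). With free RNA subtracted no member of either MHC list was measured, and H2-Ab1 and Cd74 reached at most 0.844% and 0.367% of their highest class, so no MHC change in this class is drawn from these counts. Matrix and fibrosis had 3 and 0 of 6 (2 and 0), with the connective tissue growth factor gene Ccn2 at 1.95 [1.64 to 2.28] and Sparc at 1.61, and endothelial activation 3 and 0 of 4 (2 and 0; Cxcl12 0.95). The same subtraction turned matrix and fibrosis to 0 higher and 3 lower.

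The renin-angiotensin list had 2 higher and 0 lower of 7 (0 and 0; Agtr1a 0.70). Distal sodium transport and aldosterone response genes had 4 higher and 5 lower of 17 (3 and 8), with the glucocorticoid-responsive genes Fkbp5 (1.45 [1.37 to 1.54]; 112, 126 and 344 CPM) and Tsc22d3 (1.01) and the period gene Per1 (0.96) most extreme. The male-biased list (6 and 1 of 11; median 1.36) was led by Slco1a1 (3.39 [2.51 to 4.42]), Cyp2j13 and Slc7a13 (2.34 [2.05 to 2.65]), and the female-biased list had 1 higher and 1 lower of 3 (0 and 1; Cyp4a14, and Prlr 0.77). Early segment genes had 1 higher and 0 lower of 11 (1 and 0; Slc5a12 1.51), late segment genes 8 and 0 of 10 (4 and 0; Slc7a13, Slc22a30, and Atp11a 1.19), cell cycle 1 and 0 of 4 (1 and 0; Stmn1 0.99), and leptin signalling 2 and 0 of 4 (0 and 0; Jak2 0.63). With free RNA subtracted distal sodium transport turned to 4 higher and 2 lower and cell cycle to 0 and 1 (Stmn1 -0.79) in proximal tubule-like cells. The distal sodium transport list also had 4 higher and 3 lower at a minimum of 50 CPM and 4 and 3 with the mean over cells. The higher counts of gluconeogenesis, MHC class II and tubular injury rested on the CPM scale, falling to 0, 0 and 3 with size factors. Tubular injury had 14 of 21 higher with at most 30% mitochondrial UMIs, where the cells were clustered and named anew. At Leiden resolution 2, which left out no cell, 14 injury members were also higher.

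**Figure D3:**
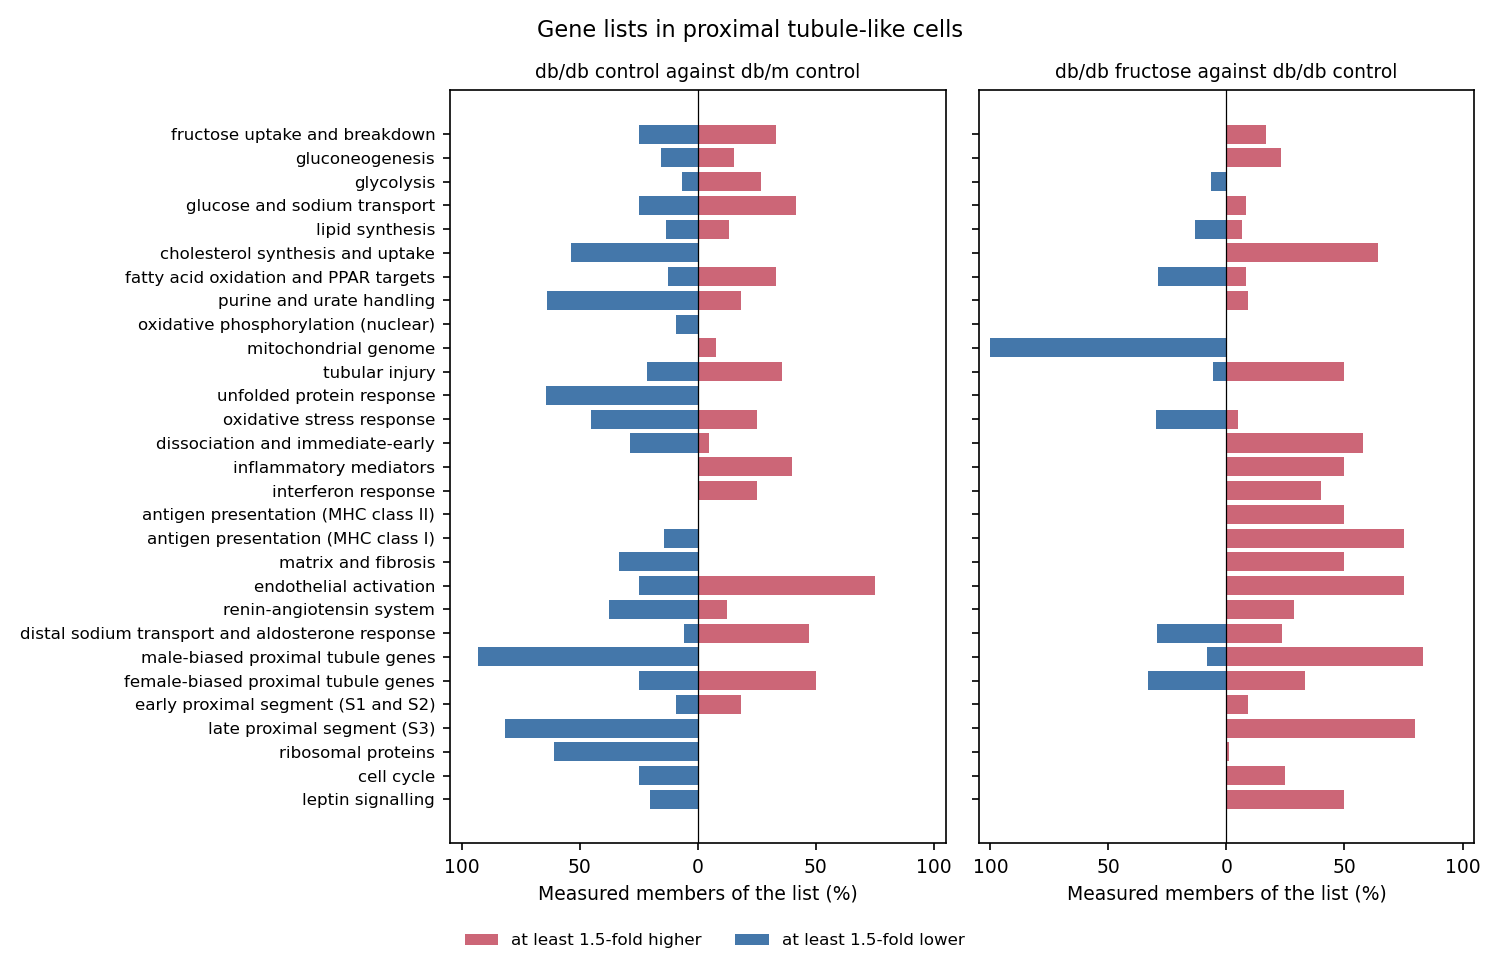
Percent of the measured members of each list at least 1.5-fold higher (to the right) or lower (to the left) in proximal tubule-like cells, for db/db control against db/m and for db/db fructose against db/db control. The bars for the male-biased list point left for db/db control against db/m, 13 of 14 members, and mostly right for fructose, 10 of 12.

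The same 4 lists were examined on fructose in the other classes, where the all-gene medians lay between 0.20 and 0.33, size factors moved ratios by -0.20 to -0.32, and size-factor counts again follow in parentheses. Thick ascending limb-like cells had 13 tubular injury genes higher and 0 lower of 19 (9 higher), led by Lcn2 (2.16 [1.89 to 2.45]), the keratin Krt19 (1.80) and the stress cytokine Gdf15 (1.44). With at most 30% mitochondrial UMIs that list had 4 higher of 18 in the thick ascending limb. Pappa2, a protease of insulin-like growth factor binding proteins, was at 29.7, 30.6 and 194 CPM (2.66 [2.40 to 2.94]) and the clock gene Nr1d2 at 1.80, whereas Nefl (-1.72), Adgrg3 (-1.19) and Pdk4 (-1.13) were lowest within the limits. Pappa2 was a leading gene of cluster 22, which held 185 and 163 cells on the control and fructose diets, and ratios within that cluster were not examined. Fatty acid oxidation had 0 higher and 8 lower of 24 (11 lower; Cyp4a10 -2.07). Cyp4a10 was also lower in proximal tubule-like cells, and free RNA is not excluded as a source of its ratio here. Cholesterol genes had 5 and 0 of 13 (2 of 11 higher; Insig1 1.22), and interferon response 2 and 0 of 6 (1 higher; Ifitm3 1.37). With free RNA subtracted both turned in the thick ascending limb, cholesterol to 0 higher and 2 lower and interferon response to 1 and 3.

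Distal convoluted tubule-like cells had 11 of 18 injury genes higher and 0 lower (7 of 17; Lcn2 2.10 [1.01 to 3.31], Gdf15 1.58, Spp1 1.43). Fatty acid oxidation had 9 lower and 0 higher of 23 (13 lower; Angptl4 -2.10), cholesterol genes 6 higher and 0 lower of 13 (6 higher; Msmo1 1.37), and interferon response 3 and 0 of 6 (1 of 5; Isg15 1.60). The interferon list turned to 0 higher and 1 lower with free RNA subtracted, and Lcn2 to -0.82 in the distal convoluted tubule with each library clustered on its own. Nr1d2 (2.18 [1.66 to 2.72]), Kap (1.503) and the splicing regulator Esrp1 (1.48) were highest within the limits, and Pdk4 (-1.34 [-1.52 to -1.16]), Slc22a12 (-0.99) and Wfdc15b (-0.89) lowest.

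Connecting tubule and principal-like cells had Nr1d1 at 5.80, 10.7 and 110.0 CPM (3.36 [2.77 to 4.01]), the hormone gene Stc1 at 153, 104 and 486 CPM (2.22 [2.02 to 2.42]) and the transcription factor Scx at 1.85, and the BMP antagonist Grem1 (-1.76 [-2.11 to -1.42]) and the phosphodiesterase Pde10a (-1.32) lowest within the limits. Tubular injury had 9 higher and 0 lower of 19 (5 of 18; Dcdc2a 1.80, Tnfrsf12a 1.31, Clu 1.06). Cholesterol genes had 7 and 0 of 11 (5 higher; Msmo1 1.67), fatty acid oxidation 0 and 7 of 22 (11 of 23 lower), and interferon response 4 and 0 of 9 (4 and 1; Ifitm3 1.87). That interferon list turned to 1 higher and 3 lower with free RNA subtracted in the connecting tubule and principal-like cells, and Ifitm3 was at -0.063 among those with 10 to 20% mitochondrial UMIs.

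Interferon response genes were higher on fructose in endothelium-like cells, 15 of 20 and 0 lower (11 higher), led by Ifi27l2a (2.90 [2.34 to 3.51]), Usp18 (1.93) and Ifit3 (1.75). Among endothelium-like cells with 10 to 20% mitochondrial UMIs the list had 2 higher and 3 lower of 18, and the median mitochondrial share of this class was 18.0% on the control diet and 7.94% on fructose. Lrg1, a secreted glycoprotein of activated vessels (ENSMUSG00000037095, chromosome 17, 56119678 to 56122001), was at 32.7, 66.6 and 295 CPM (2.15 [1.91 to 2.40]), with Slc26a10 (1.41) and Irf7 (1.40) next within the limits and Prxl2a (-1.01), Acsl1 (-0.997) and Slc22a12 (-0.99) lowest. Tubular injury had 3 higher and 0 lower of 17 (0 of 16), fatty acid oxidation 0 and 7 of 24 (8 lower), and cholesterol genes 3 and 0 of 13 (1 higher). Free-RNA subtraction turned cholesterol to 1 higher and 4 lower and injury to 0 and 2 in endothelium-like cells. Slc22a12 was at 0.047 among those with 10 to 20% mitochondrial UMIs.

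Intercalated-like cells had 11 of 13 cholesterol genes higher and 0 lower (10 higher), with Cyp51 (1.67 [0.89 to 2.50]) and Hmgcs1 (1.53). Interferon response was lower for 3 of 8 (4 with size factors; Psmb8 -1.51), fatty acid oxidation had 2 higher and 8 lower of 23 (1 and 14), and tubular injury 3 and 1 of 14 (2 and 1; C3 1.43). The injury list turned to 3 higher and 4 lower with free RNA subtracted and to 0 and 1 at a minimum of 50 CPM, and Psmb8 to 0.034 in intercalated-like cells thinned to 1000 UMIs. Per3 (2.46 [1.75 to 3.22]), Nr1d2 (2.13) and Kap (2.03) were highest within the limits, and Cbr2, a carbonyl reductase (-2.37 [-3.16 to -1.66]; 195, 112 and 21.7 CPM), Pdk4 (-1.67) and Cebpzos (-1.59) lowest. Median mitochondrial shares on fructose were 14.6% in thick ascending limb-like, 14.8% in distal convoluted tubule-like, 13.9% in connecting tubule and principal-like and 10.5% in intercalated-like cells.

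The db/db fructose and db/m libraries differ in both genotype and diet and are set side by side as levels only. In proximal tubule-like cells Kap was at 329 CPM in db/db fructose and 5466 in db/m, Slco1a1 at 10.4 and 228, Cyp4a14 at 56.3 and 2.59, and Cyp51 at 34.6 and 66.0. Slc2a5 was at 56.7 CPM in db/db fructose and 14.97 in db/m, and Nr1d1 at 103 and 11.3.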

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

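Of the tests in this part, those on cells with 10 to 20% mitochondrial UMIs, on Ehd3-detected endothelium-like cells, on podocyte-restricted markers and on the lower mitochondrial share as a source of the clock gene values were chosen only after the result was seen.

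Male-biased genes had a median log2 ratio of -2.57 in db/db control against db/m proximal tubule-like cells. Late cells were 68.5% of the placed db/m cells and 32.9% of the placed db/db cells. The median was -2.36 within early and -2.36 within late cells, against the prediction for fewer late-segment cells. The split cannot exclude that explanation, because cells were placed by late-segment genes, most of which were lower in db/db. Free RNA also reaches both parts. The higher mitochondrial share of db/db cells does not account for the difference, since among cells with 10 to 20% mitochondrial UMIs the median was -2.40. A weaker androgen signal in db/db males may lie behind the difference, and for it the female-biased list should be higher: its median was 2.12 over 4 measured members, but 0.08 without Cyp4a14, a member that other lists share. With that dependence on 1 gene, a weaker androgen signal cannot be told apart from other causes, and no hormone was measured here.

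Podocyte-like cells were a smaller share of the db/db libraries than of db/m. Poorer release of whole glomeruli would also lower the glomerular endothelium, but Ehd3-detected endothelium-like cells were 3.56% of db/db control and 3.66% of db/db fructose cells against 3.04% [2.71 to 3.39] in db/m. Whether podocytes were removed by the cell filters or left in unnamed clusters could not be settled by the planned count, barcodes with 3 or more podocyte markers, which was 2.48%, 1.31% and 2.63% and included 81, 185 and 237 endothelium-like cells. Barcodes with at least 2 of 6 podocyte-restricted markers were 1.01% [0.844 to 1.19], 0.0943% [0.0610 to 0.139] and 0.2502% [0.186 to 0.329] of all barcodes, which argues against removal by the filters as the whole account. They numbered 136, 25 and 51, against 103, 8 and 12 podocyte-like cells, so filters or naming may account for part of the difference. Loss of podocytes in the animal and loss during dissociation both stay open.

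Clock genes were higher in db/db fructose than in db/db control cells. Kidneys taken at different clock phases are a candidate explanation: relative to the median gene of proximal tubule-like cells, the antiphase genes Arntl, Npas2 and Clock had a median log2 ratio of -1.50 (-1.50, -1.60 and -0.32), and 8 clock genes were at least 1.5-fold higher by their median in 5 of 6 classes. The lower mitochondrial share of the fructose library scales all other genes up, but relative to the median gene the 8 clock genes still had a median of 1.68, with Dbp at 4.02, Ciart at 3.12, Nr1d1 at 2.15 and Per3 at 1.95. Per2 and Hlf, at -0.32 and -0.27, did not share that direction. The time of day of collection is not known here, so a change of phase by diet and a difference in collection time both stay open.

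An unnamed cluster with a median mitochondrial share of 38.3%, with 60, 2583 and 327 cells of the db/m, db/db control and db/db fructose libraries, made up 15.89% of db/db control and 2.038% of db/db fructose cells. An unnamed cluster with Ccn2, Adamts5, Serpine2 and Itga8 among its leading genes held 2.505% of the db/db fructose cells (81, 94 and 402 cells). An unnamed cluster with Slc12a3 and Slc34a1 among its leading genes and a median of 3444 UMIs per cell made up 0.8061% of db/db control and 0.4612% of db/db fructose cells (4, 131 and 74 cells), and whether its cells are doublets was not tested. Dividing cells, with Mki67 and Top2a, were left unnamed and made up 0.4549% of db/db fructose cells (18, 36 and 73 cells). Barcodes with over 50% mitochondrial UMIs, which were left out, were 19.96% of the db/db control barcodes, against 16.8% [16.1 to 17.4] in db/m and 5.19% [4.89 to 5.50] in db/db fructose.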

How the results depend on the processing

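Of the tests in this part, those with automatic doublet calls and with cells of 10 to 20% mitochondrial UMIs were chosen only after the results were seen, and the other 13 settings, the gene lists and the naming rule for genes before the data were examined. No paired analysis was possible because each group gave 1 library. Genotype differs alone by design between the control-diet libraries, and diet between the db/db libraries. With 1 library per group, neither can be parted from dissociation, collection time or differences between mice. Sequencing depth also differs between the libraries, and was equalised per cell only in the setting with thinned cells. The number of mice per library is not known here. The estimate of free RNA is high in all 3 libraries, though remaining doublets can raise it and its subtraction can remove too much. The mitochondrial share differs between the libraries in each class.

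Over the 8 main lists in both comparisons, 170 of 235 values for 16 results stayed within 1.5-fold of the main count, 58 moved further and 7 changed direction. For the other lists described these numbers were 941, 233 and 44 of 1218 values (82 results), and for all 29 lists 646, 187 and 24 of 857 in proximal tubule-like cells (58 results, 13 with a change of direction) and 3031, 1082 and 180 of 4293 in the other classes (290 results, 101 with a change of direction). Each value counts only the higher or only the lower members. A list with equal main counts of both could not change direction, as with gluconeogenesis, lipid synthesis and MHC class II in db/db against db/m. MHC class II thus counts as unchanged with at most 30% mitochondrial UMIs, although its measured members were lower there. These tallies therefore overstate stability. Of 4548 gene values (357 ratios), 3657 stayed within the counting interval, 861 lay outside it and 30 were counted as changing sign. Only ratios of at least 1.5-fold under the main setting could be counted so. Sign changes of smaller ratios are among the other values. Of the class shares other than the proximal tubule, 195 of 252 values (36 shares) stayed within their interval and 57 moved. Shares of proximal tubule-like cells stayed in 9 of 21 values and moved in 12.

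Under all settings run, male-biased genes in db/db against db/m proximal tubule-like cells had 12 to 14 members lower and 0 higher, the unfolded protein response 7 to 10 lower and 0 higher, and cholesterol genes 2 to 11 lower and 0 higher. On fructose cholesterol genes had 2 to 10 members higher and 0 lower, and fatty acid oxidation 5 to 11 lower. The main counts for the values below were, for db/db against db/m, 2 gluconeogenesis, 2 lipid synthesis, 5 injury, 1 interferon and 0 MHC class II members higher. On fructose they were 2 fructose, 3 gluconeogenesis, 9 injury, 2 interferon and 2 MHC class II members higher and 2 lipid synthesis, 7 fatty acid oxidation and 6 oxidative stress members lower. Values below are for proximal tubule-like cells unless another class is named. The cause of a difference was not tested, except that minimums of 1 and 50 CPM change which members are measured, size factors and leaving out mitochondrial genes shift all ratios of a class, and thinning removes shallow cells.

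With a minimum of 1 CPM, db/db against db/m had 9 injury, 6 interferon and 1 MHC class II members higher, and the female-biased list turned to 2 higher and 4 lower. On fructose 15 injury, 6 interferon and 6 MHC class II members were higher, and lipid synthesis turned to 3 higher and 2 lower. Injury in endothelium-like db/db cells turned to 6 higher and 5 lower.

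With a minimum of 50 CPM, db/db against db/m had 1 lipid synthesis and 2 injury members higher, and fructose 3 injury and 1 MHC class II members higher and 2 oxidative stress members lower. Lipid synthesis on fructose turned to 1 higher and 0 lower, and distal sodium transport to 4 higher and 3 lower. In distal convoluted tubule-like db/db cells fatty acid oxidation turned to 1 higher and 3 lower, and in intercalated-like cells injury on fructose to 0 higher and 1 lower. At this minimum no member was measured of the interferon, inflammatory, endothelial activation and cell cycle lists in the proximal tubule, of MHC class II for db/db against db/m there, and of the interferon list in thick ascending limb-like and distal convoluted tubule-like cells, so no value is given.

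At Leiden resolution 0.5, 0 interferon members were higher in db/db. At Leiden resolution 2 the proximal tubule-like share was 59.99% in db/m and 55% in db/db fructose. In db/db 1 lipid synthesis member was higher, injury turned to 3 higher and 11 lower and inflammatory mediators to 0 higher and 2 lower, and Cxcl10 to -0.38. On fructose 5 fructose, 14 injury, 5 interferon and 5 MHC class II members were higher.

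With at least 500 genes per cell the proximal tubule-like shares were 57.59%, 44.92% and 55.11%. In db/db 1 lipid synthesis member was higher, injury turned to 3 higher and 11 lower, interferon response to 0 higher and 1 lower, inflammatory mediators to 0 higher and 2 lower, and Cxcl10 to -0.45. On fructose 5 fructose, 14 injury, 4 interferon and 5 MHC class II members were higher.

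With at most 30% mitochondrial UMIs the shares were 62.95%, 55.22% and 58.61%. In db/db 1 lipid synthesis member was higher, injury turned to 3 higher and 12 lower, interferon response to 1 higher and 2 lower, inflammatory mediators to 0 higher and 3 lower, and endothelial activation to 1 higher and 2 lower. C3 turned to -0.0038, Irf1 to -0.15, Cxcl10 to -0.72 and Icam1 to -0.12 in db/db. Injury in distal convoluted tubule-like db/db cells turned to 5 higher and 3 lower, and Clu in the thick ascending limb on fructose to -0.064. On fructose 5 fructose, 14 injury, 5 interferon and 5 MHC class II members were higher.

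With automatic doublet calls the shares were 41.66% in db/db control and 52.39% in db/db fructose, and 5 gluconeogenesis members were higher on fructose. With doublets kept the db/db control share was 41.81%, 0 interferon members were higher in db/db, and injury in connecting tubule and principal-like db/db cells turned to 3 higher and 4 lower.

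With each library clustered on its own the db/db fructose share was 56.52%, and 5 fructose, 15 injury, 4 interferon and 5 MHC class II members were higher on fructose. Injury in db/db turned to 2 higher and 1 lower in distal convoluted tubule-like and 4 higher and 3 lower in endothelium-like cells. Vcam1 turned to 0.16 in db/db, and Lcn2 on fructose to -0.82 in the distal convoluted tubule.

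With cells thinned to 1000 UMIs, db/db had 1 lipid synthesis and 0 interferon members higher, and fructose 4 interferon and 4 MHC class II members higher and 1 lipid synthesis member lower. Injury in endothelium-like db/db cells turned to 5 higher and 4 lower, and in intercalated-like cells Stat2 to -0.30 in db/db and Psmb8 to 0.034 on fructose.

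Among cells with 10 to 20% mitochondrial UMIs, 2 interferon members were higher in db/db and 0 gluconeogenesis members on fructose. On fructose glucose and sodium transport turned to 0 higher and 1 lower, purine and urate handling to 0 and 1, and interferon response in endothelium-like cells to 2 and 3. In db/db injury in distal convoluted tubule-like cells turned to 3 higher and 2 lower, and cholesterol in endothelium-like cells to 5 and 4. Signs changed for Slc22a12 (0.047, fructose) and Msmo1 (0.49, db/db) in endothelium-like, and Gbp2 (0.45, db/db), Ifitm3 (-0.063, fructose) and Bst2 (-0.24, fructose) in connecting tubule and principal-like cells.

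With the free-RNA profile subtracted, db/db had 4 gluconeogenesis and 1 lipid synthesis members higher, and fructose 5 gluconeogenesis, 3 injury and 1 interferon members higher and 1 lipid synthesis and 11 fatty acid oxidation members lower. No MHC class I or class II member was measured. Matrix genes turned to 3 higher and 1 lower in db/db and to 0 and 3 on fructose, where distal sodium transport turned to 4 higher and 2 lower, ribosomal proteins to 0 and 14, and cell cycle to 0 and 1. Elsewhere in db/db the lists turned to 1 higher and 3 lower (connecting tubule and principal-like, fatty acid oxidation), 3 and 2 (distal convoluted tubule, injury), 2 and 1 (endothelium, cholesterol) and 3 and 0 (thick ascending limb, cholesterol). On fructose they turned to 1 and 3 (connecting tubule and principal-like, interferon), 0 and 1 (distal convoluted tubule, interferon), 1 and 3 (thick ascending limb, interferon), 0 and 2 (thick ascending limb, cholesterol), 1 and 4 (endothelium, cholesterol), 0 and 2 (endothelium, injury) and 3 and 4 (intercalated, injury).

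Under the same subtraction signs changed on fructose in proximal tubule-like cells for Cp (-0.74), Col18a1 (-0.80), Rpl22l1 (-3.43) and Stmn1 (-0.79), for Ifi27 in distal convoluted tubule-like (-0.48) and thick ascending limb-like cells (-1.15), for Sqle in the thick ascending limb (-0.55), and for Cyp51 (-1.24) and Clu (-4.59) in the endothelium. In db/db they changed for Kap in connecting tubule and principal-like cells (3.42), Cyp51 (0.38) and C3 (-0.70) in the endothelium, and Mvd (0.00069) and Cyp51 (1.40) in the thick ascending limb.

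With the mean over cells, 1 lipid synthesis and 0 interferon members were higher in db/db, distal sodium transport on fructose turned to 4 higher and 3 lower, and injury in endothelium-like db/db cells to 4 and 2. With size factors, 2 interferon members were higher in db/db, and 1 fructose, 0 gluconeogenesis, 3 injury and 0 MHC class II members on fructose. Glucose and sodium transport on fructose turned to 0 higher and 1 lower, ribosomal proteins to 0 and 2, and injury in db/db to 3 and 1 in distal convoluted tubule-like and 5 and 4 in endothelium-like cells.

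With mitochondrial genes left out, 2 interferon members were higher in db/db, and 1 gluconeogenesis, 5 injury and 1 MHC class II members on fructose. Glucose and sodium transport on fructose turned to 0 higher and 1 lower, and injury in db/db to 3 and 1 in distal convoluted tubule-like and 5 and 4 in endothelium-like cells. This scaling moved all log2 ratios by 0.17 in distal convoluted tubule-like, 0.17 in connecting tubule and principal-like and 0.12 in endothelium-like db/db cells, and on fructose by -0.18, -0.14, -0.17, -0.20, -0.16 and -0.17 in proximal tubule, thick ascending limb, distal convoluted tubule, connecting tubule and principal, endothelium and intercalated-like cells.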

Other observations

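Of the tests in this part all were chosen only after the result was seen, and none was repeated under other settings.

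Mononuclear phagocyte-like cells numbered 86, 351 and 308 in the db/m, db/db control and db/db fructose libraries, so only fructose against control within db/db had over 100 cells on both sides. Interferon response genes were higher on fructose for 12 of 19 and lower for 1, with a median log2 ratio of 0.73 at percentile 100 (7 and 1 relative to the median gene, whose ratio was 0.21). Ifi27l2a was at 606, 109.7 and 559 CPM (2.35 [2.03 to 2.69]), Ifi213 at 2.31 and Irf7 at 1.11, whereas Irf1 was at -0.77. The median mitochondrial share of this class was 7.84%, 20.9% and 9.88%, all 13 mitochondrial genes were lower on fructose, and the list was not examined at a matched mitochondrial share. In endothelium-like cells that list had 2 higher and 3 lower of 18 among cells with 10 to 20% mitochondrial UMIs. For Ifi27l2a the low value of the 3 is that of the db/db control library, and the db/m value rests on few cells. The class can hold macrophage-like, monocyte-like and dendritic-like cells. Whether the ratios of this class, here and below, follow a different mix of these cells on fructose was not tested.

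Among genes with at least 50 CPM in the higher library and at least 25% of their highest class in either, the highest ratio in mononuclear phagocyte-like cells was that of the chemokine gene Ccl17, at 3.57, 5.90 and 51.1 CPM (3.11 [1.78 to 4.81]), followed by Lcn2 (2.85), and the monocyte chemoattractant gene Ccl12 stood at 289, 33.0 and 158 CPM (2.26). Neutrophil-like cells were too few to be among the classes compared for this limit, so Lcn2 was not set against them. Hmox1, the haem oxygenase gene, was lowest at 57.1, 184 and 54.6 CPM (-1.75 [-2.26 to -1.27]), then Cxcl1 (-1.25), with Icam1 at -1.07. Among list members under that minimum Cxcl10 was at 46.4, 47.2 and 10.7 CPM (-2.14). Inflammatory mediators had 2 higher and 4 lower of 18, and MHC class II 0 and 1 of 8, with Cd74 at 30349, 20414 and 21213 CPM. Cholesterol synthesis and uptake had 8 higher and 1 lower of 13 (median 1.01; 7 and 1 relative to the median gene), fatty acid oxidation 2 and 7 of 24 (1 and 9), cell cycle 8 and 0 of 13 (7 and 1) and tubular injury 10 and 1 of 19 (6 and 3). Free RNA was not subtracted for this class.

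The thin limb-like class was a mixture. At resolution 2, 79, 16 and 86 of its cells took the proximal tubule name, 0.794% [0.629 to 0.989], 0.0985% [0.0563 to 0.160] and 0.536% [0.429 to 0.661] of the db/m, db/db control and db/db fructose cells, and 82, 56 and 93 stayed thin limb-like. The proximal tubule-named part had median depths of 11282, 6192.5 and 10978 UMIs, with the injury gene Havcr1 at 32.8, 0 and 21.96 CPM (30, 0 and 21 counts), Vcam1 at 177, 300 and 100.4 CPM and Cd74 at 1766, 977 and 1285 CPM. Havcr1 gave 1, 2 and 9 counts in the whole proximal tubule-like class under the main settings. Spp1 was at 1607, 4593 and 6358 CPM in the same part. The part that stayed thin limb-like had Cryab at 9179, 8066 and 9912 CPM, Aqp1 at 5205, 5152 and 3934 CPM and Fst at 2207, 2660 and 3496 CPM. These few cells therefore fall in or out of the proximal tubule-like class with the resolution, and their share was lowest in db/db control.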
